A study of Xenopus laevis with 3 samples.

How the data were processed

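RNA was measured in heads of Xenopus laevis embryos at about stage 41, with 1 array for each of the groups CoMO, xMLTK-MO and xSox6-MO. Per the labels' protocols, embryos from in vitro fertilisation were kept at 22 °C and injected with 10 ng of morpholino per cell, and heads were cut off 72 hours after fertilisation. Total RNA was DNase-treated and column-purified, and biotinylated cRNA was made from 150 ng of it with a 3' in vitro transcription kit, per the labels' protocols. The name CoMO is not spelled out in the labels, and whether the groups came from the same clutch or how many heads were pooled is not given in the sources used here. Groups were taken from the treatment label.

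The deposited values are probe-set intensities on a linear scale with nearly the same distribution on each array. Per the submitters' processing notes they were made with RMA, a method that corrects background, quantile-normalises the arrays and summarises the probes of a probe set, and per the series' design text the software was GeneChip operating Software 1.4 and GeneSpring GX 11.0.2. Because RMA values are usually logged and these were not, log2 was taken here before any difference. Quantile normalisation forces the arrays to a common distribution, so a change of all transcripts together would not be seen, and each value is relative to the rest of its array. The arrays reached from an intensity of 4.15 to 22711 in CoMO, 4.10 to 23020 in xMLTK-MO and 3.83 to 23719 in xSox6-MO. The highest negative control probe set, of 23, had an intensity of 23.3, 26.2 and 21.0. Detection calls and raw scans were not analysed here.

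Of 32635 probe sets, 15505 had 1 gene symbol in the platform annotation, 279 had several and 16851 had none. Control probe sets numbered 96, and probe sets with several symbols were left out of the genes. Symbols were matched through the gene identifier for 15394 probe sets, which changed 2 of them, and kept as annotated for 111, using a RefSeq gene table of assembly Xenopus_laevis_v10.1 for names only. Probe sets of a symbol were averaged on the log2 scale, giving 11303 genes, 2704 of them with more than 1 probe set, and homeologs (.L and .S) were kept apart. The level filter kept 7258 genes with a mean log2 intensity over the 3 arrays of at least 6.51, an intensity of 91.4, the median of all probe sets. No coordinates are given, since the annotation's build is not named.

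Each comparison is the difference of log2 intensities of a pair of arrays. With 1 array per group there are no residual degrees of freedom, so no test was run, and genes were counted at a difference of at least 2-fold. A gene not above the highest negative control on an array has only a bound there, and its fold is given as at least the ratio of the brighter value to that control; this rule was chosen after seeing the data. Members of a list counted as lower or higher among genes above the negative controls were above them on at least 1 array of the pair, a count also added after seeing the data. For it, homeologs not above the controls on either array were left out before averaging. A value below the highest control of its array was raised to that control. The control differs between arrays, so the sign of a dim gene's difference can come from the controls. Where differences of both morphants from CoMO were compared, 1000 sets of unchanged arrays were simulated with the noise of the xMLTK-MO minus xSox6-MO difference in 20 level bins, once with its robust and once with its full spread.

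For 30 gene lists fixed before the data were examined, homeologs were averaged to 1 gene and the median difference was set against 10000 random lists of equal size matched on mean level in 10 bins. A list of at least 3 measured genes is said to stand apart at or below percentile 2.5 or at or above percentile 97.5, a description of these arrays that treats genes as independent; 1.4 of the 28 lists with enough genes would do so by chance. The lists are knockdown targets, cartilage matrix, chondrogenic regulators, neural crest and pharyngeal arch, bone, fibrous connective tissue, skeletal muscle, cardiac muscle, lens, photoreceptor, neuron, neural progenitor, glia and myelin, epidermis, ciliated cells, cement and hatching gland, erythrocyte, endothelium, myeloid cells, liver with gut and pancreas, pituitary and thyroid, pigment cells, inner ear, p53 pathway and apoptosis, innate immune and interferon, cell cycle, immediate early and stress MAPK, heat shock and endoplasmic reticulum stress, retinoid with thyroid hormone and matrix remodelling enzymes, and reference genes. A further 10 lists were written after the preset lists had been computed and before their own medians were seen. Differences of some of their members had by then been computed. Preset lists held 17 of 28 pancreas, 9 of 19 liver and 6 of 16 slow and cardiac-type sarcomere genes. Members such as cela1.1.S and tnni1.2.L were also among the named genes of largest difference. Named genes are members of the cartilage lists past 2-fold, 5 fixed cartilage genes, up to 4 members of each other list with the largest differences, and for each comparison and for shared differences the 10 largest in each direction among genes passing the filter, passing over placeholder symbols. Other list members named beside these were chosen after their values were seen.

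The steps were tested on simulated data for xMLTK-MO versus CoMO over 7258 genes. The simulated noise was normal and independent between probe sets, with the robust spread of the xMLTK-MO minus xSox6-MO difference. Outlying probe sets and deviations of a whole sample were thus left out. Of 100 genes planted at a log2 difference of 1.5, 98 passed 2-fold, of 100 planted at 0.5, 1 did, and of 7058 unchanged genes 0 did. That last count checks the steps and does not measure false calls in these data. Over 9242 genes with homeologs merged, 12 of 200 random lists stood apart, and 49 of 50 lists of 12 genes shifted by 0.3 did. Alternatives were no level filter, a filter at percentile 75, thresholds of 1.5-fold and 3-fold, lowess centring (fraction 0.3), renewed quantile normalisation, the brightest probe set, no probe sets with shared probes, the probe set as unit, level-filtered list members, separate homeologs, and lists without their most different member. A floor at the negative controls and centring on 27 hybridisation controls were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.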

Results

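The transcriptome of Xenopus laevis tadpole heads was compared after knockdown of 2 proteins, the protein kinase MLTK and the transcription factor Sox6, in a study of cartilage formation. Embryos had received 10 ng of morpholino per cell early in cleavage and were collected 72 hours after fertilisation, at about stage 41, a swimming tadpole in which the cartilages of the head skeleton are forming. The 3 groups were heads of embryos given xMLTK-MO, xSox6-MO or CoMO, and CoMO served as the control in the comparisons made here. Each group had 1 array, so there were no replicates, no difference could be set against a spread between embryos, and every value describes these 3 arrays only. The number of arrays limits the precision. Of 32635 probe sets, 15505 carried 1 gene symbol, and these gave 11303 genes, 7258 of them at or above the level filter. The median intensity was 92.7 on the CoMO array, 91.1 on the xMLTK-MO array and 89.8 on the xSox6-MO array, and 72.9%, 71.3% and 73.7% of probe sets were brighter than the highest negative control of the array. X. laevis carries many genes as a pair of homeologs, marked .L and .S for the long and short chromosomes of its subgenomes, and these were kept apart for single genes. Depletion of the 2 proteins was not measured in these data. The mRNA of the targets could not be checked either, since 0 annotated probe sets carried the symbol map3k20 (MLTK) or sox6. The genes acan, sox5 and runx2 were likewise without an annotated probe set.

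The first comparison asked which genes differed in heads with MLTK knocked down. Cartilage matrix genes were lower on the xMLTK-MO array than on the CoMO array, as were genes of the cell cycle and of protein folding, while several pancreatic enzyme genes, immediate early genes and p53 pathway genes were higher. Of 12 measured cartilage matrix genes, 11 were above the negative controls on at least 1 of the arrays, and of these 10 were lower and 4 at least 2-fold lower. The list had a median log2 difference of -0.61, below that of all 10000 level-matched random lists. Matrilin 1 (matn1.L), a cartilage matrix protein, had an intensity of 107 in CoMO and was not above the negative controls in xMLTK-MO, which makes it at least 4.10-fold lower. The genes of otospiralin, a protein best known from the inner ear (otos.L and otos.S), were 3.35-fold and 2.37-fold lower, chondromodulin (cnmd.S), a cartilage protein that restrains vessel growth, was 2.55-fold lower, and matrilin 4 (matn4.L) was 2.04-fold lower. The fibrillar collagen gene of cartilage, col2a1.L, differed less, with a log2 intensity of 12.56 in CoMO and 12.23 in xMLTK-MO. The collagen IX genes col9a1.L, col9a2.L and col9a3.L had log2 differences of -0.47, -0.66 and -0.43.

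The regulators of chondrocyte formation did not stand apart as a group. The median over 13 measured genes was -0.05, at the 27.5th percentile of random lists, and 0 of them were 2-fold higher or lower. Sox9, the transcription factor required for cartilage formation, had log2 intensities of 10.53 in CoMO and 10.52 in xMLTK-MO for sox9.L, and 11.29 and 11.03 for sox9.S. The related gene sox8.L differed by -0.58 and bmp4.S by 0.65, while the joint gene gdf5.L, not above the negative controls in xMLTK-MO, was at least 1.90-fold lower. The neural crest and pharyngeal arch list, genes of the precursors of the head cartilages, had a median of 0.17 over 21 genes, at the 99.3rd percentile, with hand2.S at 0.93, msx1.L at 0.84 and sox10.L at -0.88.

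**Figure D1:**
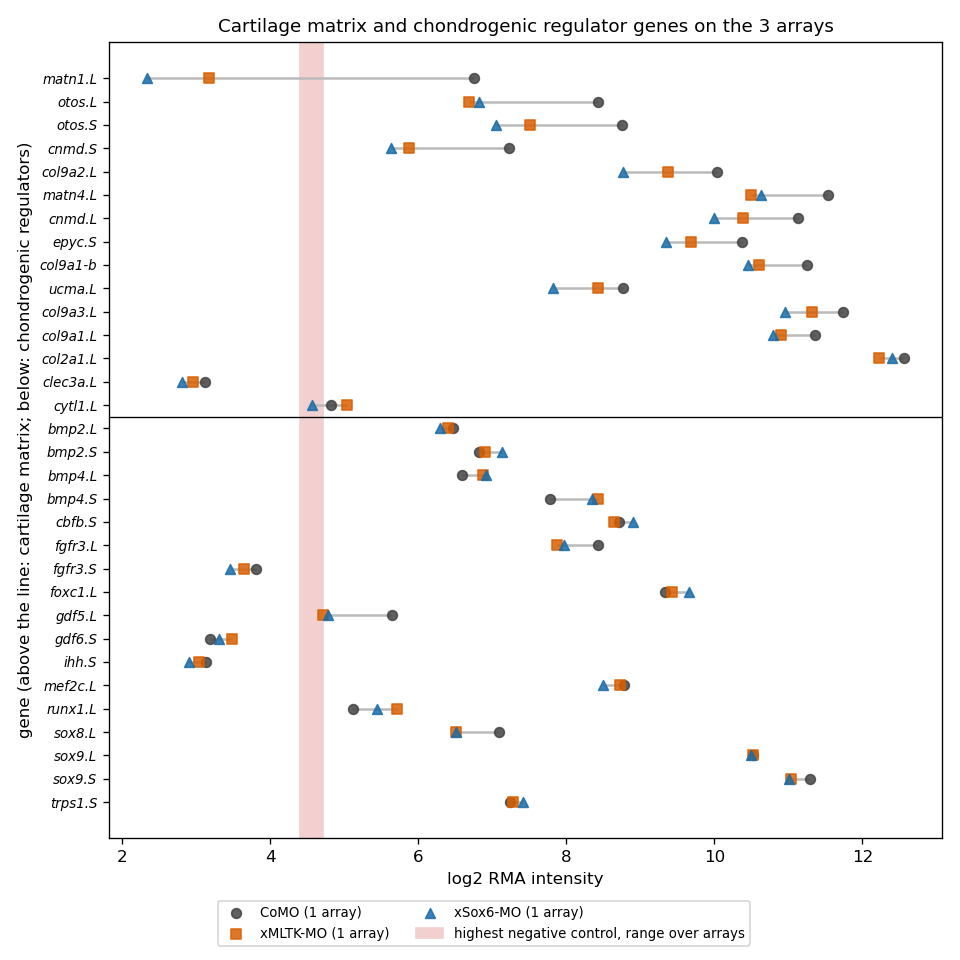
Log2 RMA intensity (x axis) of each measured gene of the cartilage matrix list (above the line) and the chondrogenic regulator list (below it) on the CoMO array (circles), the xMLTK-MO array (squares) and the xSox6-MO array (triangles), with 1 array per group and no error bars; the shaded band spans the highest negative control of the 3 arrays. Most matrix genes lie further left on both morphant arrays, with matn1.L below the band there, whereas sox9.L lies at 10.53, 10.52 and 10.49.

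Among all 7258 genes, 93 were at least 2-fold higher and 57 at least 2-fold lower in xMLTK-MO than in CoMO, and 97.9% lay within 2-fold. Centred on hybridisation controls, the counts were 127 and 38. The 10 named genes with the largest positive differences among these 7258 genes included 5 of pancreatic enzymes. Those were the elastase gene cela1.1.S, with a log2 difference of 3.91, the chymotrypsin-type protease genes ctrc.L and ctrl.L, 9.52-fold and 7.12-fold higher, the pancreatic disulfide isomerase gene pdia2.L, 9.37-fold higher, and the bile salt-activated lipase gene cel.2.S, 7.80-fold higher. The others were c1qtnf9b.L, at least 20.4-fold higher because its CoMO value of 7.45 was not above the negative controls, the astacin protease gene astl3a.1.L at 13.0-fold, crisp1.5.S at 8.06-fold, sds.L at 7.11-fold and the cathepsin E gene ctse.L at 5.96-fold. Of the liver, gut and pancreas list, 5 of 27 genes were at least 2-fold higher and 0 lower, with a median of 0.21. Many of its members were not above the negative controls, and with values raised to those controls the median was 0.17, the difference between the controls themselves, and no longer stood apart. The insulin genes ins.L and ins.S, not above the negative controls in CoMO, were at least 7.54-fold and 10.5-fold higher.

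Proliferation and stress genes formed further groups. Of 26 cell cycle genes above the negative controls 26 were lower, and the median over 30 genes was -0.61, among them the spindle checkpoint kinase gene bub1.L at -1.29, the anaphase activator gene cdc20.S at -0.94 and the replication helicase gene mcm4.L at -0.87. In the p53 and apoptosis list the median over 13 genes was 0.50 and 2 genes were at least 2-fold higher, the cyclin-dependent kinase inhibitor gene cdkn1a.L at 4.75-fold and the exonuclease gene aen.L with a log2 difference of 1.32. The immediate early and stress MAPK list, chosen because MLTK is a kinase upstream of stress MAPKs, had 18 of 21 genes above the negative controls higher and a median of 0.39, with fos.S 4.76-fold, junb.L 3.68-fold and ier2.L 2.43-fold higher. Of 15 heat shock and endoplasmic reticulum stress genes above the negative controls, 13 were lower and 4 at least 2-fold lower, with a median of -0.64. The small heat shock protein genes hspb1.L and hspb1.S differed by -1.54 and -1.03 and the chaperone gene hsp90b1.S by -1.11, whereas the stress transcription factor gene ddit3.L differed by 1.11.

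Among muscle genes the skeletal muscle list had a median of -0.22 over 32 genes, with acta1.S at -1.46, while the cardiac muscle list had a median of 0.07 over 14 genes although the ventricular light chain gene myl2.S was 3.07-fold lower and the natriuretic peptide gene nppb.L differed by 1.46. Among genes passing the level filter, the largest named negative differences were those of the slow troponin gene tnni1.2.L, 4.69-fold lower, smim11a.L, 4.68-fold lower, otos.L, the crystallin gene crygbl.4.S, 3.13-fold lower, erlin2.L at 3.13-fold, gsta4.S at 3.12-fold, myl2.S, hspb1.L, the keratin gene krt62.L at 2.84-fold and chmp1b.S at 2.67-fold. The lens list had a median of -0.18 over 19 genes, the erythrocyte list -0.17 over 15 genes with alas2.L at -1.35 (-0.14 and no longer apart after renewed quantile normalisation), and the cement and hatching gland list -0.51 over 3 genes, of which astl3a.1 went the other way. The myeloid list had a median of 0.24 over 11 genes with the eosinophil peroxidase gene epx.L at 1.72, and the innate immune list 0.18 over 16 genes (0.14 and no longer apart with the brightest probe set) with socs3.L at 1.73 and the complement gene c3.L at 1.30. The bone list held only 4 measured genes, with a median of 0.63 that was 0.32 without the collagenase gene mmp13.S and then no longer stood apart.

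In all, 14 of the 28 lists with at least 3 measured genes stood apart from random lists in this comparison, 7 lower and 7 higher, where chance gives 5%, a percentile that treats the genes of a list as independent. Besides the chondrogenic regulators, the lists that did not stand apart had medians of 0.07 (cardiac muscle, 14 genes), -0.04 (fibrous connective tissue, 14 genes), -0.10 (photoreceptor, 20), 0.05 (neuron, 23), -0.12 (neural progenitor, 15), -0.003 (glia and myelin, 3), -0.03 (epidermis, 35), 0.13 (ciliated cells, 15), 0.01 (endothelium, 8), 0.08 (pituitary and thyroid, 7), -0.19 (pigment cells, 5), 0.03 (retinoid, thyroid hormone and matrix remodelling enzymes, 18) and -0.09 (reference genes, 11). Only tecta.2.S of the inner ear list was measured, and it was not above the negative controls in xMLTK-MO and so at least 1.63-fold lower. Centring on hybridisation controls adds 0.10 to each difference from CoMO, which turns the sign of medians between -0.10 and 0, those of the chondrogenic regulators and reference genes included. Poly-A control transcripts, added to the RNA, differed more, by a median of -0.27, and centring on them was not run. A shift of that size would also turn the sign of the skeletal muscle, lens and erythrocyte medians.

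The second comparison asked the same of heads with Sox6 knocked down. Cartilage matrix genes were again lower than in CoMO, lens and photoreceptor genes were lower, and neural crest and arch genes were higher. Of the 11 cartilage matrix genes above the negative controls on at least 1 of the arrays, 11 were lower and 5 at least 2-fold lower. The list of 12 had a median log2 difference of -0.93, below all 10000 random lists. matn1.L was at least 5.10-fold lower, otos.S 3.25-fold, otos.L 3.07-fold, cnmd.S 3.01-fold and col9a2.L 2.42-fold lower. The proteoglycan gene epyc.S was 2.05-fold lower, the cartilage secreted protein gene ucma.L 1.93-fold and matn4.L 1.88-fold lower, and col2a1.L differed by -0.16. The chondrogenic regulators had a median of 0.07 over 13 genes, at the 86.2nd percentile, with 0 genes 2-fold higher or lower, log2 intensities of 10.49 for sox9.L and 11.01 for sox9.S, sox8.L at -0.57 and gdf5.L at -0.86. The neural crest and arch list had a median of 0.30 with 15 of 19 genes above the negative controls higher, among them msx1.S at 1.03 and hoxa2.S at 0.92, while sox10.L was at -0.95.

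Eye genes were another group of lower genes, beside the skeletal muscle, cell cycle and heat shock genes given below. Of 15 lens genes above the negative controls 15 were lower and 7 at least 2-fold lower, and the median over 19 genes was -0.50. The crystallin genes crygbl.4.S and crygbl.1.L, whose close paralogs may share probes, were 29.4-fold and 7.18-fold lower, the alpha crystallin gene cryaa.S 4.26-fold lower, and the lens filament gene bfsp1.L differed by -1.34. Of 18 photoreceptor genes above the negative controls 17 were lower and 5 at least 2-fold lower, and the median over 20 genes was -0.48. They included the rod arrestin gene sag.S at -1.40, the disc membrane gene rom1.S at -1.29 and the rod transducin gene gnat1.S at -1.19.

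Over all 7258 genes, 71 were at least 2-fold higher and 77 at least 2-fold lower in xSox6-MO than in CoMO, and 98.0% lay within 2-fold. Centred on hybridisation controls, the counts were 113 and 52. The largest named positive differences among these 7258 genes were those of c1qtnf9b.L, at least 12.7-fold, astl3a.1.L at 9.75-fold, crisp1.5.S at 7.99-fold, the serine dehydratase gene sds.L at 6.35-fold, xepsin.S at 5.91-fold, phyhdlb.L at 5.80-fold, satpb.L at 5.11-fold, the glucose-6-phosphatase gene g6pc1.1.L at 4.01-fold, the chemokine gene cxcl8.L at 3.97-fold and the arginase gene arg2.S at 3.75-fold. Besides the crystallins and otos.S, the largest named negative differences among them were those of tnni1.2.L, 4.44-fold lower, myl2.S at 3.96-fold, anxa1.2.L at 3.79-fold, hspb1.L at 3.66-fold, the mitochondrial ADP/ATP carrier gene slc25a4.L at 3.64-fold and tnni1.S at 3.24-fold.

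Some pancreatic genes were higher than in CoMO, although the liver, gut and pancreas list did not stand apart, with a median of -0.03 and 7 higher and 9 lower of 16 genes above the negative controls. ins.S was at least 5.49-fold, ins.L at least 3.41-fold and the pancreatic lipase gene pnlip.L at least 3.10-fold higher, the last against at least 2.08-fold in xMLTK-MO, and pdia2.L was 2.84-fold, cela1.1.S 2.73-fold and cel.2.S 2.46-fold higher. Of the list, 3 of 27 genes were at least 2-fold higher and 0 lower.

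The skeletal muscle list had a median of -0.30 with 24 of 29 genes above the negative controls lower, although the myogenic regulator gene myog.S differed by 1.58, and the cardiac list had a median of 0.06. The cell cycle list had a median of -0.36 with 25 of 26 such genes lower, and the heat shock and endoplasmic reticulum stress list a median of -0.61. Immediate early genes had a median of 0.27, with fos.S at 0.93 and junb.L at 0.92. The p53 list had a median of 0.07 and did not stand apart, with 8 of 12 genes above the negative controls higher and 4 lower. As in xMLTK-MO, 2 of its genes were at least 2-fold higher, cdkn1a.L at 4.35-fold and aen.L at 2.42-fold. The erythrocyte list had a median of -0.21 and the bone list 0.32, the latter 0.08 without mmp13.S. The pigment cell list had a median of 0.30 over 5 genes that no longer stood apart, at 0.25, without its most different gene. The innate immune median of 0.11 became -0.04 when values below the negative controls were raised to them. The highest control was dimmer in xSox6-MO than in CoMO, at log2 4.39 against 4.54. Members dim on both arrays thus took a negative difference from the controls alone. Of the 11 innate immune genes above the controls, 8 were higher and 3 lower.

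For the xSox6-MO array, 12 of 28 lists stood apart from random lists, 7 lower and 5 higher. Besides the chondrogenic regulators, medians of the lists that did not were 0.06 (cardiac muscle), 0.07 (p53 pathway and apoptosis), -0.07 (fibrous connective tissue), -0.07 (neuron), 0.15 (neural progenitor), -0.36 (glia and myelin), -0.06 (epidermis), -0.09 (ciliated cells), -0.20 (cement and hatching gland), 0.10 (endothelium), 0.12 (myeloid cells), -0.03 (liver, gut and pancreas, as above), -0.11 (pituitary and thyroid), -0.003 (retinoid, thyroid hormone and matrix remodelling enzymes) and -0.003 (reference genes). In the inner ear list tecta.2.S differed by -0.86. Centring on hybridisation controls adds 0.15 here and turns the sign of medians between -0.15 and 0. The poly-A controls had a median difference of -0.35, and a shift of that size would also turn the sign of the skeletal muscle and erythrocyte medians. Centring on them was not run.

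**Figure D2:**
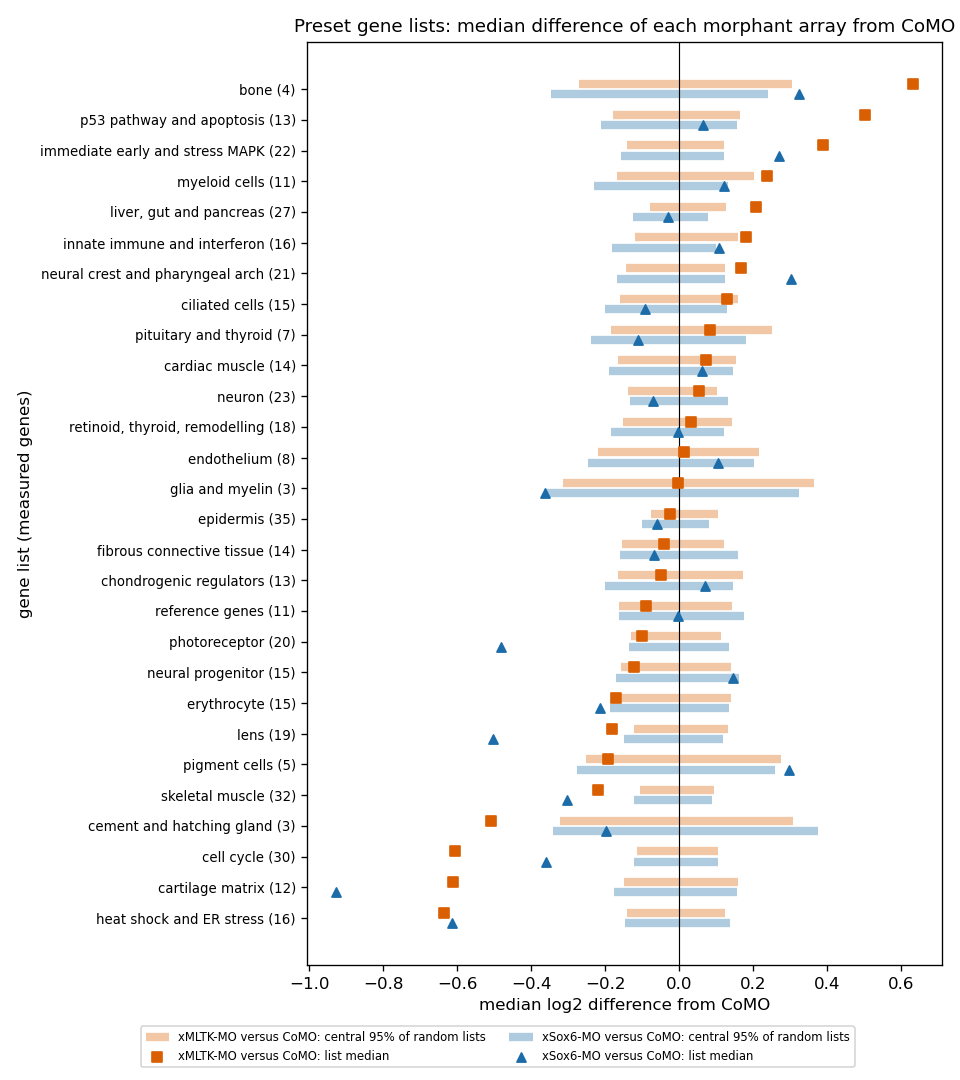
Median log2 difference from CoMO (x axis) of each preset gene list with at least 3 measured genes (number in brackets, y axis) on the xMLTK-MO array (squares) and the xSox6-MO array (triangles); bars span the central 95% of medians of 10000 level-matched random lists for each comparison. Cartilage matrix lies at -0.61 and -0.93, outside its bars on both arrays, while chondrogenic regulators lie at -0.05 and 0.07, inside them.

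Both knockdowns were then set side by side, since the study targeted 2 proteins in the same setting. Against CoMO, 45 genes were at least 2-fold higher on both morphant arrays, 29 at least 2-fold lower on both, and 0 went opposite ways past 2-fold; centred on hybridisation controls, 65 were higher and 16 lower on both. Among the 10 named genes passing the level filter with the largest shared positive differences were c1qtnf9b.L, astl3a.1.L, crisp1.5.S, sds.L, xepsin.S and arg2.S. The 10 such genes with the largest shared negative differences included tnni1.2.L, otos.L, otos.S, myl2.S, hspb1.L, crygbl.4.S and the troponin gene tnnc1.S, at -1.32 in xMLTK-MO and -1.28 in xSox6-MO. Across the 7258 genes, which are not independent replicates, the differences correlated with Pearson's r of 0.724 and Spearman's rho of 0.661, and 73.5% had the same sign. Both comparisons use the same CoMO array, which alone gives a mean r of 0.50 and 66.7% of the same sign in 1000 simulations of unchanged arrays. The observed covariance was 0.104 against a simulated mean of 0.0243, or 0.0397 with the full spread of the noise. The simulations gave at most 2 genes higher and 3 lower on both arrays, and independent lists would share 0.910 and 0.605 genes. The simulations gave the 3 arrays equal noise, so a CoMO array that deviated more than the others would raise these values further. Part or all of the excess may therefore come from the shared control, which as a single array could not be split.

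**Figure D3:**
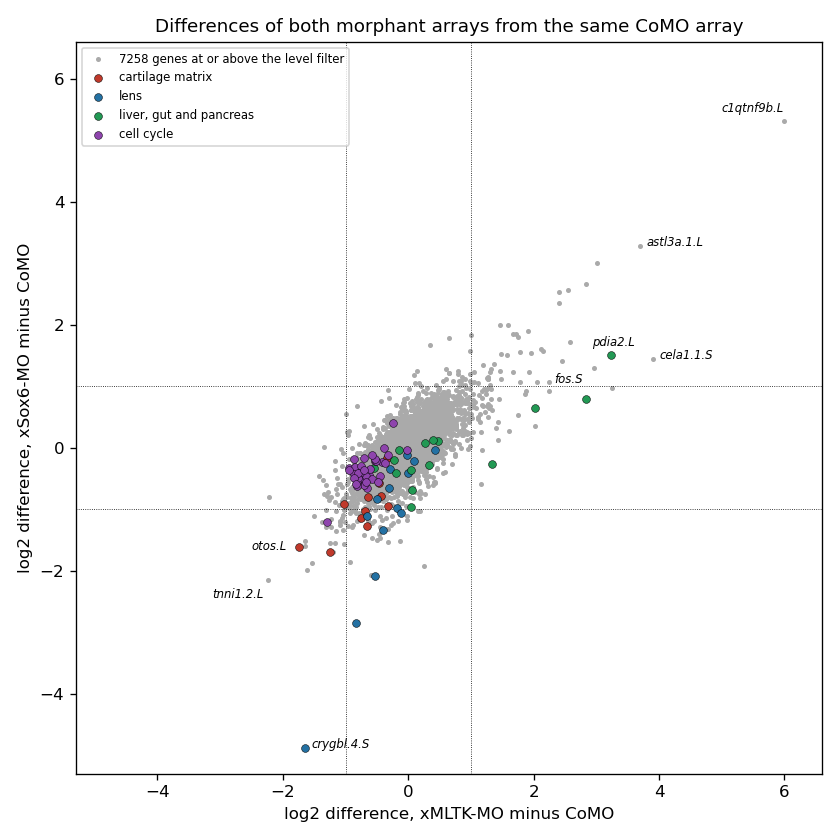
Log2 difference from CoMO on the xMLTK-MO array (x axis) against that on the xSox6-MO array (y axis) for 7258 genes at or above the level filter (1 array per group), with members of 4 preset lists in colour and dotted lines at 2-fold. Both axes share the CoMO array, and 45 genes lie past the lines in the upper right and 29 in the lower left.

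The last comparison set the knockdowns directly against each other. The xMLTK-MO array had higher levels of lens and photoreceptor genes and of several pancreatic enzyme genes than the xSox6-MO array, and lower levels of pigment cell and cell cycle genes. The photoreceptor median was 0.63 with 3 of 20 genes at least 2-fold higher, and the lens median 0.38 with 3 of 19. crygbl.4.S was 9.37-fold, cela1.1.S 5.49-fold, ctrc.L 4.82-fold, anxa1.2.L 4.51-fold, ctrl.L 4.12-fold, crygbl.1.L 4.02-fold, pdia2.L 3.30-fold and cel.2.S 3.17-fold higher in xMLTK-MO. The retinol-binding protein gene rbp2.L differed by 1.76 and the vitamin B12 carrier gene tcn2.S by 1.66. Cartilage matrix was higher in xMLTK-MO than in xSox6-MO, by a median of 0.33 with 8 of 10 genes above the negative controls higher, 0 of them by 2-fold, and the median of the chondrogenic regulators was 0.02.

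The pigment cell median was -0.70 over 5 genes, with the melanin synthesis gene tyrp1.L at -0.50 in xMLTK-MO and 0.30 in xSox6-MO against CoMO. The cell cycle median was -0.24 with 25 of 26 genes above the negative controls lower in xMLTK-MO. Largest in the negative direction were the tryptophanyl-tRNA synthetase gene wars1.L at -1.54, igf3.L at -1.49, smim11a.L at -1.42, chid1.L at -1.36, the intermediate filament gene prph.S at -1.32, thdl18.S at -1.27, rpa3.S at -1.23, the ribonucleotide reductase gene rrm2b.S at -1.23, gtsf1.L at -1.19 and snrnp40.S at -1.17. In total 35 genes were at least 2-fold higher and 16 at least 2-fold lower in xMLTK-MO than in xSox6-MO, and 99.3% lay within 2-fold.

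The liver, gut and pancreas median between the morphants was 0.22 with 5 of 27 genes at least 2-fold higher in xMLTK-MO, while pnlip.L was 1.49-fold lower there. The list median was 0.32 with values below the negative controls raised to them, where it no longer stood apart. The p53 list was higher in xMLTK-MO for 12 of 12 genes above the negative controls with a median of 0.25, immediate early genes had a median of 0.15, ciliated cell genes 0.28, neuron genes 0.12 and skeletal muscle genes 0.10, the last no longer apart at 0.099 without its most different gene. The endothelium median was -0.18 and no longer stood apart, at -0.11, with homeologs counted separately. Of 28 lists, 12 stood apart, 3 lower and 9 higher. Besides the chondrogenic regulators, the lists that did not had medians of -0.06 (neural crest and arch), 0.18 (bone), 0.07 (fibrous connective tissue), 0.10 (cardiac muscle), -0.06 (neural progenitor), 0.36 (glia and myelin), -0.01 (epidermis), 0.19 (cement and hatching gland), 0.06 (erythrocyte), 0.10 (myeloid cells), 0.15 (pituitary and thyroid), 0.17 (innate immune), -0.05 (heat shock), 0.10 (retinoid, thyroid hormone and matrix remodelling enzymes) and -0.06 (reference genes).

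The CoMO array stood further from the others than they stood from each other. The intensities of the morphant arrays correlated with r = 0.981 across genes, against 0.966 for each with CoMO, and the variance that a single array added on its own was 0.104 for CoMO, which equals the covariance above, 0.0399 for xMLTK-MO and 0.0398 for xSox6-MO. The ratio of 3' to 5' signal of gapdh, a measure of RNA and labelling quality, was 1.85 in CoMO, 1.99 in xMLTK-MO and 2.16 in xSox6-MO. The same ratio of dap, a bacterial transcript added to the RNA as a poly-A control, was 6.14, 7.10 and 7.30 in the same order. Poly-A spike controls had median differences from CoMO of -0.27 and -0.35 on the xMLTK-MO and xSox6-MO arrays, and hybridisation controls -0.10 and -0.15. Where a gene's homeologs both passed the level filter, in 1165 pairs, their differences from CoMO correlated with r = 0.647 across pairs for xMLTK-MO and 0.590 for xSox6-MO. Of 18 .L copies past 2-fold in xMLTK-MO, 18 had an .S copy with the same sign and 6 an .S copy past 2-fold the same way, and in xSox6-MO these were 19 and 10 of 20. Between the morphants r was 0.485, and 1 of 4 .S copies passed 2-fold the same way. Binding of transcripts from a homeolog to the other copy's probes was not checked.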

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

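The count of probe sets without a gene name was chosen after the differences of named genes had been seen. The comparisons above use named genes, so these probe sets are data outside them, drawn to attention because they hold differences of the same size. Of 16765 such probe sets, controls left out, 6449 passed the level filter. Against CoMO, 75 were at least 2-fold higher and 48 at least 2-fold lower on the xMLTK-MO array, and 58 were higher and 64 lower on the xSox6-MO array. On both morphant arrays 31 were higher and 25 lower. Between the morphants, 33 were at least 2-fold higher and 20 lower in xMLTK-MO. Which genes they measure was not analysed here, and no explanation was tested.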

How the results depend on the processing

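The floor at the negative controls, the centring on hybridisation controls the counts of list members above the negative controls and the 10 later lists were chosen after the results were seen; the other settings were planned. The cartilage matrix medians stood apart and those of the chondrogenic regulators did not under every setting run, the former ranging from -0.663 to -0.510 in xMLTK-MO and from -0.947 to -0.773 in xSox6-MO. Counts past 2-fold stayed within 1.5 times under lowess centring, renewed quantile normalisation, the brightest probe set, exclusion of shared probes and the floor. Thresholds, filters and the unit change how many genes can be counted. In xMLTK-MO versus CoMO, 93 higher genes became 158 without a filter, 38 at percentile 75, 301 at 1.5-fold, 34 at 3-fold and 204 as probe sets, and 57 lower became 87, 30, 300, 7 and 128. In xSox6-MO versus CoMO, 71 higher became 120, 26, 320, 18 and 150, and 77 lower became 39 at percentile 75, 346 at 1.5-fold, 13 at 3-fold and 166 as probe sets. Between the morphants, 35 higher became 63, 16, 179, 11 and 82, and 16 lower became 28, 6, 124, 0 and 47. The 45 genes higher on both arrays became 76 without a filter, 16 at percentile 75, 162 at 1.5-fold and 13 at 3-fold, and the 29 lower became 15 at percentile 75, 148 at 1.5-fold and 5 at 3-fold. Centring on hybridisation controls shifts the median of all genes by 0.10 in xMLTK-MO and 0.15 in xSox6-MO against CoMO, and by -0.03 between the morphants. It gave 127 higher and 38 lower genes in xMLTK-MO, 113 and 52 in xSox6-MO, and 65 and 16 on both arrays. The same-sign share of 73.5% was 72.4% without a filter and 74.8% with this centring.

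Of the values of single named genes under these settings, 4231 stayed within the spread of genes of like level and 80 did not, with 0 sign reversals of differences past 2-fold.

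Over the preset and later lists, a median that had not stood apart came to do so in 34 combinations of list, comparison and setting. Of these, 12 arose with separate homeologs. Not standing apart is thus no stable call for such lists. Other list medians no longer stood apart. The cause was not tested. Without the most different member this held for bone (0.318 in xMLTK-MO, 0.081 in xSox6-MO), pigment cells in xSox6-MO (0.250), innate immune genes in xMLTK-MO (0.173), and between the morphants skeletal muscle (0.099) and endothelium (-0.122). With level-filtered members it held for erythrocyte genes in xMLTK-MO (-0.188), pigment cells (0.299) and innate immune genes (0.200) in xSox6-MO, and endothelium between the morphants (-0.190). With renewed quantile normalisation it held for erythrocyte genes in xMLTK-MO (-0.142) and endothelium between the morphants (-0.177), and with separate homeologs for the latter (-0.112). With the brightest probe set it held for innate immune genes (0.143 in xMLTK-MO, 0.097 in xSox6-MO), and without shared probes for skeletal muscle between the morphants (0.105). With the floor it held for liver, gut and pancreas in xMLTK-MO (0.171) and between the morphants (0.316), values set by the floors of the arrays since many members lie below them, and for skeletal muscle between the morphants (0.106). The innate immune median in xSox6-MO reversed to -0.042 with the floor, where members dim on both arrays took a negative difference from the floors alone. The respiratory chain median in xSox6-MO reversed from -0.080 to 0.075 with hybridisation-control centring. Lists with fewer than 3 members left under a setting gave no value there: level-filtered bone, glia, myeloid, pituitary and posterior Hox lists, and glia and cement gland without a member. Signal over the negative controls limits what dim genes can show, and folds of genes not above them are bounds. No paired analysis was possible because each group has 1 array.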

Other observations

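The lists in this part were written after the preset lists had been seen, and the tests of a general delay, of homeolog pairs and of the CoMO array's own variance were chosen after the result was seen. Slow and cardiac-type sarcomere genes were lower on both morphant arrays, with medians of -0.59 in xMLTK-MO and -0.65 in xSox6-MO over 16 genes, 6 of which are also in a preset list. Its members tnni1.2.L, tnni1.S, myl2.S and tnnc1.S were also among the named genes of largest negative difference. The low medians are therefore no independent support. With values below the negative controls raised to them, 5 and 6 genes were at least 2-fold lower. They differed little between the morphants (-0.06). Genes of matrix secretion and collagen processing had medians of -0.20 and -0.26, with 23 and 25 of 29 genes above the negative controls lower. Among them were the collagen chaperone gene serpinh1.S at -0.88 and -0.86 and the sulfate donor synthesis gene papss2.S at -0.83 and -1.05. The gene ugdh.L, which makes a precursor of glycosaminoglycans, was at -0.32 and -1.32, but its homeolog ugdh.S was at -0.05 and -0.235. The list median between the morphants was 0.07.

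Cholesterol synthesis genes had medians of -0.25 in xMLTK-MO and -0.51 in xSox6-MO over 13 genes, and 0.32 between the morphants, with the sterol demethylase gene cyp51a1.S at -0.57 and -1.47. Lists of housekeeping machinery lay closer to 0. Ribosomal protein genes had medians of -0.005, 0.07 and -0.07 in xMLTK-MO versus CoMO, xSox6-MO versus CoMO and between the morphants, proteasome genes -0.08, 0.02 and -0.10, and tRNA synthetase genes -0.12, -0.10 and 0.05. Centring on hybridisation controls adds 0.10 in xMLTK-MO and 0.15 in xSox6-MO and so turns the sign of small negative medians among them. The ribosomal protein median in xSox6-MO no longer stood apart, at 0.045, with the brightest probe set. Respiratory chain genes had medians of -0.02, -0.08 and 0.07, of which the xSox6-MO value turned to 0.075 with centring on hybridisation controls.

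Cartilage matrix genes were lower on both morphant arrays. The tables argue against level-dependent scaling, since the medians after lowess centring were -0.597 in xMLTK-MO and -0.940 in xSox6-MO, against central 95% ranges of random lists of -0.142 to 0.166 and -0.176 to 0.161. The same delay in every late-differentiating tissue stays open. The cartilage median minus the pooled median of 71 lens, photoreceptor and skeletal muscle genes was -0.433 (95% bootstrap interval over genes -0.907 to -0.095) in xMLTK-MO and -0.489 (-0.902 to -0.058) in xSox6-MO. However, an equal delay lowers each gene by its own rate of change with stage, which was not measured. The slow and cardiac-type sarcomere medians were -0.59 and -0.65, but some members of that list were also among the genes of largest negative difference. Fewer cartilage cells, lower matrix gene levels per cell after either knockdown and a CoMO sample that differed as a whole also stay open.

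Several pancreatic genes were higher than in CoMO on both morphant arrays, most of them highest in xMLTK-MO, and the pancreas list, 17 of whose 28 genes are in a preset list, had medians of 0.26 against CoMO, with 9 genes at least 2-fold higher, 0.06 in xSox6-MO, with 3 genes at least 2-fold higher and 0 lower, and 0.26 between the morphants. After lowess centring the xMLTK-MO median was 0.223, at percentile 99.99, which argues against level-dependent scaling. However, 18 of the 33 gene symbols of this list were not above the negative controls on any array. With values raised to those controls the median was 0.171, set by the controls, and no longer stood apart. Counted with dim homeologs left out and values raised to the controls, 14 of 14 genes were higher in xMLTK-MO, 10 of them at least 2-fold. Of these, cela1.5.L counted as higher only because the xMLTK-MO control was brighter, and its measured difference was -0.40. Counted the same way in xSox6-MO, 10 of 13 genes were higher, 5 of them at least 2-fold, and 3 were lower. More trunk tissue in the dissected heads may be a source, and it cannot be told apart from a difference within the head: the liver median was 0.189 (percentile 99.79), higher as trunk tissue would make it, while the posterior Hox median was 0.164 (percentile 95.51) with 15 of its 17 gene symbols not above the negative controls on any array. Of the 19 liver genes, 9 are in a preset list. Counted with dim homeologs left out and values raised to the controls, 13 of 18 liver genes were higher and 5 lower in xMLTK-MO. Among them c9.L differed by 1.78 and kng1.L by -0.24. The 1 posterior Hox gene above the controls in this comparison, hoxd8.L, differed by 0.77. The abundant rbp4.S had log2 intensities of 13.1 in CoMO and 13.1 in xMLTK-MO, a level at which a small added share may not show. In xSox6-MO the liver and posterior Hox medians were -0.06 and 0.02, and between the morphants 0.36 and 0.18.

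Many differences from CoMO were shared by both morphants. Measurement noise of the CoMO array that is independent between probe sets would not repeat between homeologs, but the mean difference correlated with r = 0.648 over 1031 homeolog pairs passing the level filter, leaving out probe sets marked as having shared probes, against -0.095 to 0.088 for shuffled pairs. The CoMO array's own variance of 0.104 exceeded those of the morphants, as a CoMO sample that differed as a whole in clutch, stage, dissection, RNA quality or labelling would give and as a shared effect of both knockdowns would give, and with 1 control array these cannot be told apart. A difference between injected morpholinos unrelated to their targets could also be shared and was not tested.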
